A study of Mus musculus with 28 samples.

How the data were processed

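C2C12 is an immortalised mouse myoblast line whose cells leave the cell cycle and fuse into multinucleated myotubes when serum is lowered. Per the labels, cells were grown in medium with 20% fetal bovine serum (growth medium, GM) and, near confluence, moved to medium with 3% horse serum (differentiation medium, DM). Strand-specific RNA-seq covered 18 libraries, 3 in each of 6 groups: GM and 12, 24, 48, 60 and 96 h in DM. ATAC-seq, in which a transposase tags open chromatin, covered 4 libraries, 2 in GM and 2 at 60 h. Hi-C, which maps contacts between distant parts of the chromosomes after digestion with MboI, covered 6 libraries, 3 in GM and 3 at 60 h. Groups, times and replicate numbers were taken from the sample titles, since the protocol text gives varying last time points from one sample to the next. The labels call the replicates biological and do not describe separate cultures, so p-values measure the spread between these samples, which may be technical.

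The authors deposited whole-number read counts per gene, with Ensembl gene identifiers, biotypes and symbols, not scaled between libraries. The submitters' processing notes name STAR, RSEM 1.3.0, SAMtools 1.9, DESeq2, edgeR, deepTools 2.5.2 and genome build mm10, without the role of each tool. How whole-number counts came from a tool that gives estimated counts is not given in the sources used here. The deposited ATAC-seq peak lists, 1 broad list per condition for 2 libraries, give for each peak a fold enrichment over the local background, a ratio, and −log10 q values. Per the submitters' processing notes, Bowtie2 2.2.6 and MACS2 2.2.7 were among the tools. Whether reads or calls were pooled over the 2 libraries, and the cutoff of the lists, are not given in the sources used here. Because there is 1 list per condition, no test between conditions could be made on the peaks, and the authors' fold and q of a peak were used only to describe, rank or filter peaks within a list. The deposited topologically associating domains (TADs) and boundaries were made on 40 kb bins of iterative-correction-normalised maps, per the labels, 1 set per condition for 3 libraries. HiC-Pro 2.9.0 is named by the submitters' processing notes, and the domain caller is not given in the sources used here. The boundary strength in the deposited files is a score of unstated scale. The deposited loop table lists loops with 25 kb anchors and the condition or conditions each was called in. It holds no count, fold or p-value, so the loops were compared by their condition only, and no count of loops past a threshold was possible. The loop caller and the meaning of a read filter of 50 in the table's name are not given in the sources used here. Signal tracks named by the labels were not used here.

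Of 49089 genes in the count table, 22315 had no count in any library and 15303 passed edgeR's filterByExpr by group. The kept genes held at least 99.95% of the counts in each library. All 18 libraries were fitted together with edgeR 4.0.16 in R 4.3.3 (TMM scaling, quasi-likelihood F test, group as the sole factor, 12 residual degrees of freedom). The Benjamini-Hochberg adjustment covered all genes tested in a contrast, and a gene was called at an adjusted p under 0.05. Contrasts were each time against GM, each step between neighbouring times, and an F test of any difference from GM. Values after ± are the standard error (SE) of the fit, computed as the size of the log2 fold change divided by the square root of F, or where so named the standard deviation (SD) over 3 libraries. Levels per library are log2 CPM (counts scaled to the effective library size) with a prior count of 2, or plain CPM. Total counts were 24.2 to 36.4 M (M stands for 10 to the power 6) per library, and the common biological coefficient of variation was 0.0621. Counts were simulated for all 18 libraries from each gene's mean over them, with 200 of 14983 genes changed at 60 h. The changed genes were not drawn from those with the lowest mean CPM. The same test of 60 h against GM recovered 85.1% of the genes changed 1.5-fold, 97.0% of those changed 2-fold and all 66 changed 4-fold. It called 10 unchanged genes. Each replicate pair differed by more than sampling noise (chi-square per degree of freedom 5.06 to 53.2 over genes with a summed count of at least 20), so each library was counted once.

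The following choices were made before the data were examined: the tests, the contrasts, the lists, the rule for named genes and most alternatives. Named genes were a panel of 20 genes of muscle differentiation and the cell cycle; the 10 called genes with the largest rise and the 10 with the largest fall at 60 h among genes with a mean log2 CPM of at least 3; the first 3 each way by the same rule in each other contrast; and in each list at most 4 called members with the largest changes, with called members that went against the list. For ATAC-seq and Hi-C the panel genes were named. Of 38 lists with 570 genes, all found in the table, 2 by an older symbol, 35 had the 3 tested members that a list test needs. The lists were myogenic factors, sarcomere, developmental sarcomere isoforms, fast fibre isoforms, slow fibre isoforms, calcium handling, myoblast fusion, neuromuscular junction, muscle energy isoforms, glycolysis, nuclear-encoded respiratory chain, mitochondrial genome, DNA replication, mitosis, cell cycle exit, Id proteins and Notch, TGF-beta and BMP response, extracellular matrix, cholesterol synthesis, immediate early genes, insulin-like growth factor axis, interferon response, unfolded protein and stress response, autophagy and proteolysis, ribosome biogenesis, CTCF and cohesin, condensin, chromatin regulators, imprinted genes, satellite and reserve cells, and markers of smooth muscle, cardiac muscle, adipocytes, bone and cartilage, neurons, endothelium, leukocytes and red cells. The lists were tested with limma 3.58.1's camera, with a preset correlation of 0.01 between genes and the Benjamini-Hochberg adjustment over lists and contrasts. Members were counted at the adjustment over all genes tested and adjusted over the list alone. The second count is printed where it differed from the first. Of 315 list tests, 57 passed with the preset correlation and not with an estimated correlation. The second adjusted p is then given beside the call.

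Peaks overlapping by at least 1 bp were counted as shared. Gene positions came from a RefSeq table on assembly GRCm38.p6, whose coordinates are those of mm10, and all positions are 1-based on that build. The table gives no strand, so the planned transcription starts were replaced by both ends of each gene. In all, 13987 of 15151 tested genes with a unique symbol (92.3%) were placed. For ATAC-seq and expression, genes were classed by peaks within 2 kb of either end, and medians were compared by a two-sided permutation test with 100000 permutations of the gene labels. Counts of peaks along genes took the gene with 10 kb each side. List totals were set against 10000 random lists of the same size matched on mean expression. For TADs, boundaries within 1 bin were counted as shared and compared with 1000 random shifts along each chromosome. For loops and expression, a gene was placed at a loop when either end lay in an anchor. For the panel genes, loops with an anchor overlapping any part of the gene were counted, so that longer genes can collect more loops. Genes are not independent replicates in these tests. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

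Alternatives were DESeq2 1.42.0, other scalings and filters, a replicate block, fits of the compared groups alone, other thresholds, each library left out in turn, an estimated correlation for the lists, and other overlaps, windows and peak filters. Chosen after seeing the data were a fit of protein-coding genes alone, a fit with a covariate for 84 transcripts that set 1 library apart, net peaks along genes, and a peak filter on 1 list alone. So were random lists matched on gene span, tests of other splits of the libraries, and the test of library or RNA quality for the 84 transcripts. Genes with near-identical copies, such as the prolactin-family 2c genes and the replication-dependent histones, share reads and their values are uncertain. Uqcrc1 carries 2 gene identifiers in the table, so its list of 26 genes has 27 tested members.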

Results

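The study followed C2C12 myoblasts from proliferation in GM through 96 h of differentiation in DM. Expression was measured by RNA-seq in 3 libraries per group, and chromatin accessibility (ATAC-seq) and chromatin contacts (Hi-C) were measured in GM and at 60 h. Total counts (mean ± SD, n = 3 libraries) were 29.7 ± 2.99 M in GM, 35.3 ± 1.03 M at 12 h, 30.4 ± 3.33 M at 24 h, 27.5 ± 3.25 M at 48 h, 28.6 ± 3.85 M at 60 h and 30.8 ± 0.433 M at 96 h. Below, log2 fold changes are given ± SE of the fit over 3 libraries per group, adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg adjustment, and adjusted p-values of lists come from camera. Genes said to rise or fall most are ranked among called genes with a mean log2 CPM of at least 3.

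The question of the whole time course was which genes changed at any time after the switch of medium. Myog, the transcription factor that drives terminal differentiation, rose at each time from 13.4 ± 0.201 CPM in GM to 803 ± 15.3 CPM at 96 h (mean ± SD, n = 3). Myod1, which commits cells to the muscle lineage, first fell from 47.0 ± 3.89 to 25.9 ± 2.50 CPM at 12 h and then rose above GM, to 94.3 ± 7.26 CPM at 96 h. Id1, an inhibitor of the MyoD family, fell from 72.8 ± 6.54 CPM to 12.0 ± 1.11 CPM at 96 h. Ccna2, the cyclin of S phase and G2, rose from 170 ± 7.85 to 266 ± 3.99 CPM at 12 h before it fell to 17 ± 0.607 CPM at 96 h. By the F test 13161 of 15303 genes (86.0%) differed at some time, and 4983 of these had a range of at least 2-fold. Among the called genes with that range, the level was highest at 96 h for 1550 and in GM for 1148. It was highest at 12 h for 961, at 24 h for 601, at 48 h for 438 and at 60 h for 285. The first principal component of the libraries held 64.2% of the variance and the second 11.3%.

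**Figure D1:**
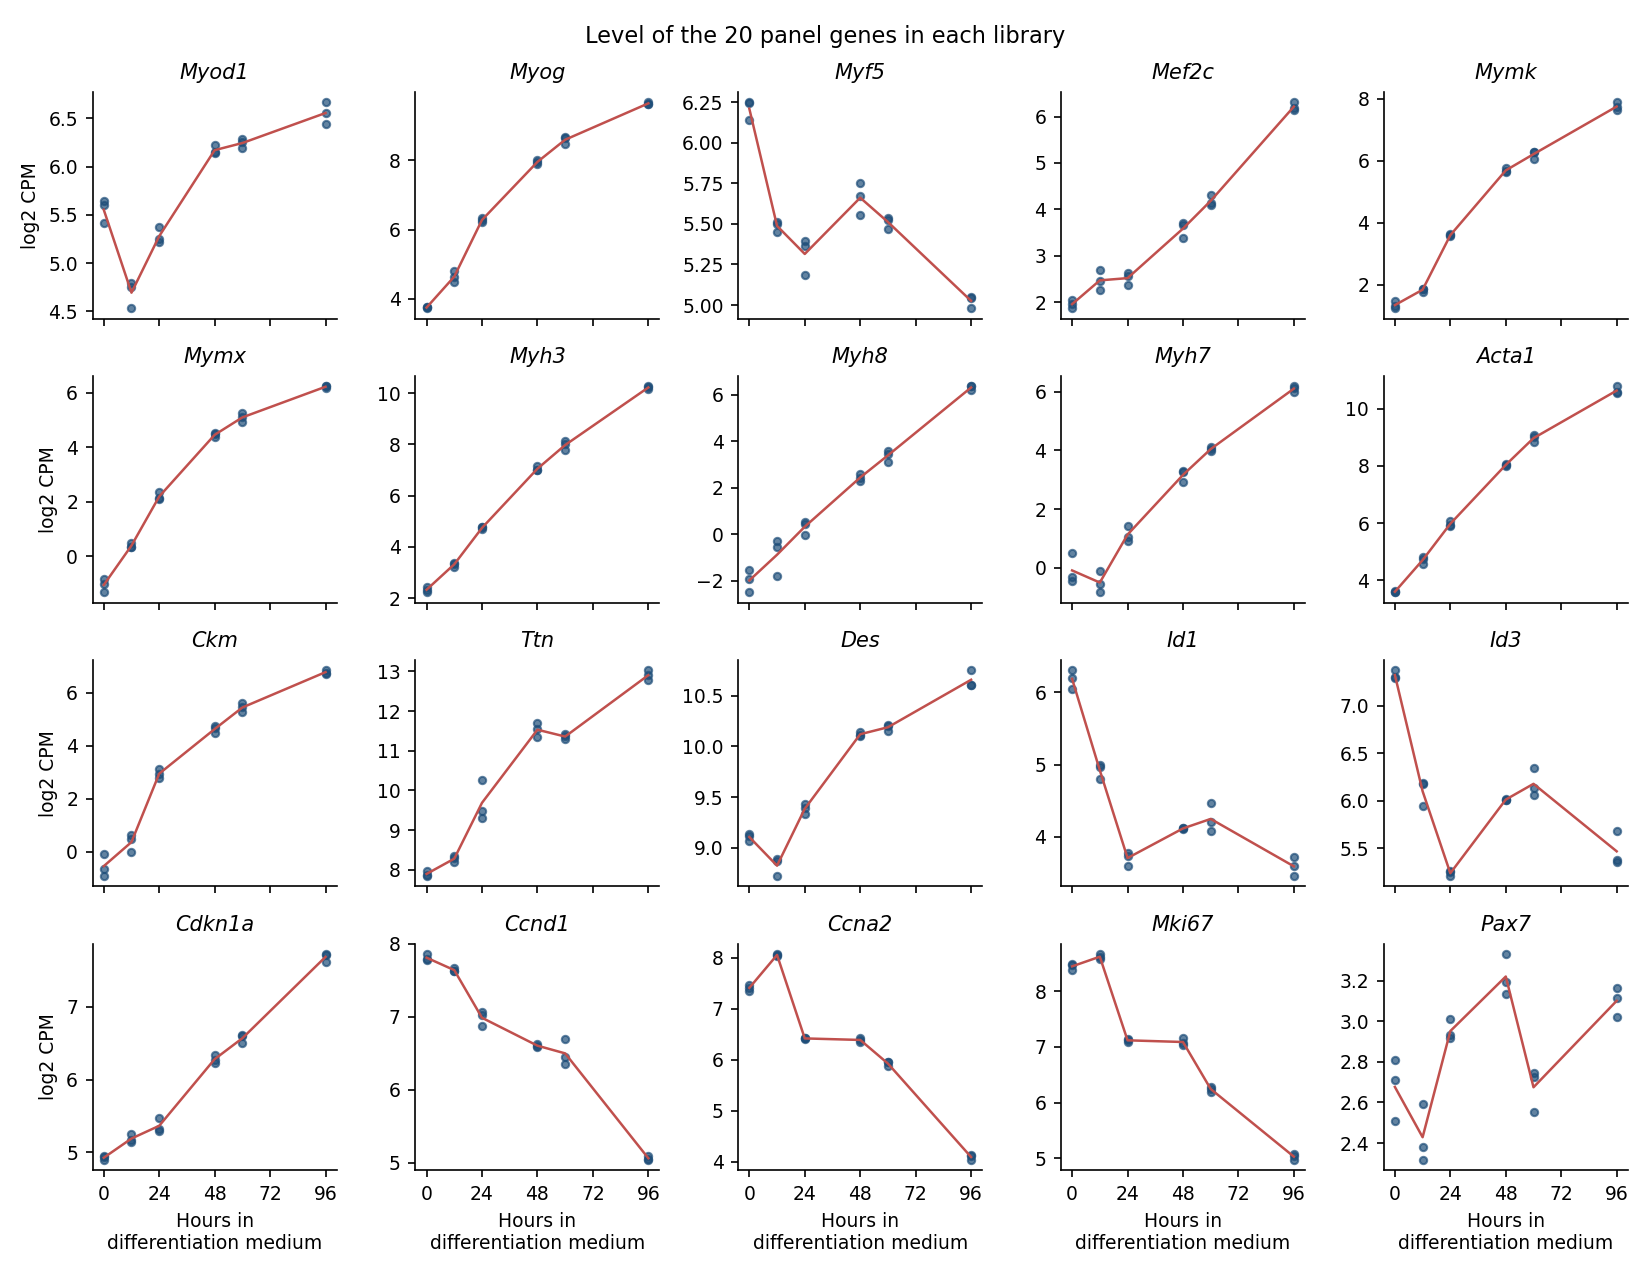
Each small plot shows the log2 CPM (vertical axis) of 1 of the 20 panel genes against hours in DM (horizontal axis, GM at 0 h), with points for the 18 libraries and a line through the group means. Myog and the sarcomere genes climbed from 12 h to 96 h, Myod1 dipped at 12 h (log2 fold change −0.86), and Ccna2 was highest at 12 h (0.64).

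**Figure D2:**
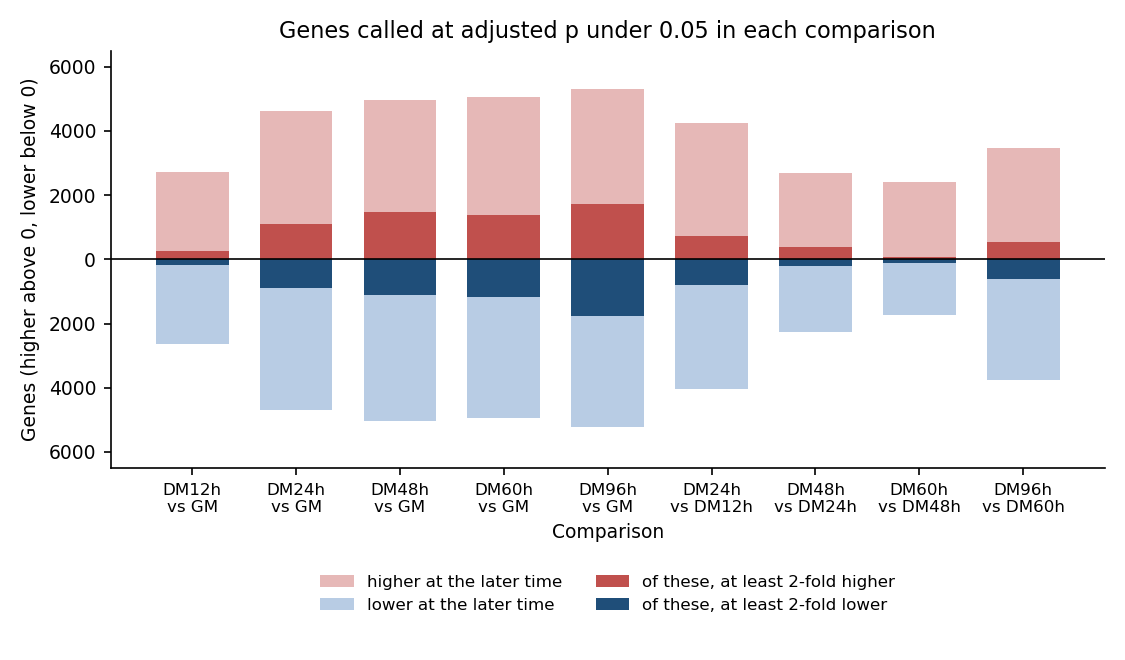
Bars give the number of genes called higher (up) and lower (down) in each of 9 comparisons, at an adjusted p under 0.05, with those changed at least 2-fold in dark. Against GM the count went from 5353 at 12 h to 10535 at 96 h, and the step from 48 to 60 h had the fewest, 4157, in this fit of all 18 libraries. In fits of the 6 libraries compared, 4937 were called in that step and the fewest, 4563, from 24 to 48 h.

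A group of transcripts moved with both time and 1 library. In the third library of the 24 h group, 84 of 7350 protein-coding genes lay at least 0.5 (log2) above the other 24 h libraries, while no other library had more than 5 such genes. They included Polr2a, which encodes the largest subunit of RNA polymerase II (1.73 higher), the perlecan gene Hspg2 (1.28), the fibronectin gene Fn1 (0.97) and the titin gene Ttn (0.87). Kmt2d, a histone methyltransferase (1.37), and Lrp1, an endocytic receptor (1.16), also belonged to them and are named here after their values were seen. Of the 84, 98.8% lay lower at 12 h than in GM, against 50.2% of the other genes, and all 84 lay higher at 96 h than at 60 h, against 46.9%. Polr2a was at 62.7 ± 3.45 CPM in GM, 10.3 ± 0.398 CPM at 60 h and 61.2 ± 4.82 CPM at 96 h, and at 25.3 ± 19.1 CPM at 24 h (SD, n = 3). The libraries also differed in composition: protein-coding genes held 70.9 ± 0.613% of the counts in GM and 65.5 ± 0.355% at 60 h, the lowest share of the 6 groups. The signal recognition particle RNAs Rn7s1 and Rn7s2, chosen after their values were seen, together held 17.3 to 24.3% of the counts of a library.

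**Figure D3:**
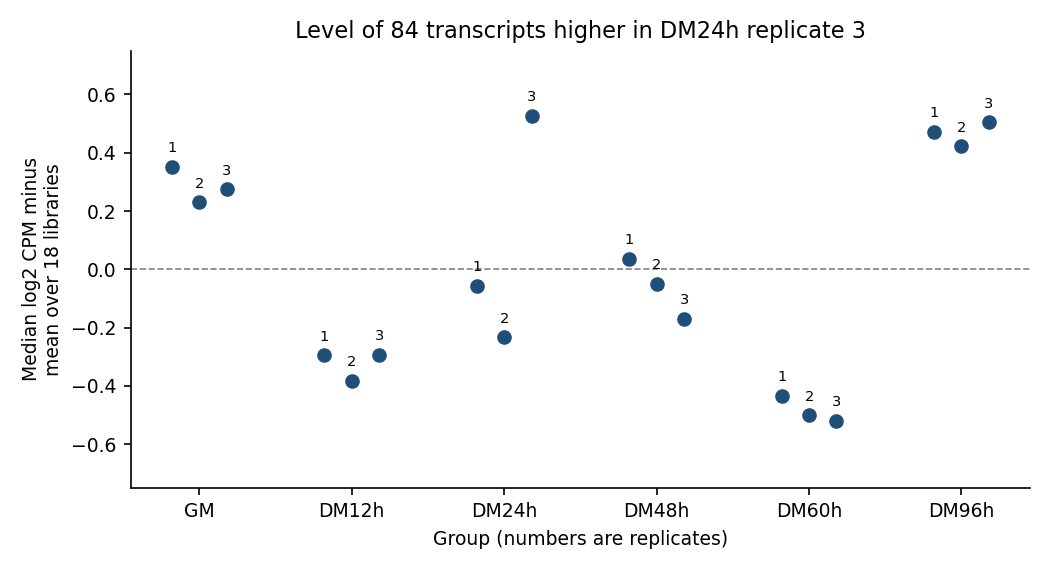
Each point is 1 of the 18 RNA libraries, by group (horizontal axis), at the median level of the 84 transcripts, as log2 CPM minus the mean over the 18 libraries (vertical axis). GM libraries lay at 0.23 to 0.35 and 96 h libraries at 0.42 to 0.50, those of 60 h at −0.43 to −0.52, and the 24 h libraries at −0.06, −0.23 and 0.53.

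After 12 h in DM, against GM, genes of cholesterol synthesis and of mitosis rose together, and genes of ribosome biogenesis fell. The transferrin receptor Tfrc, which imports iron, had the largest rise among genes with a mean log2 CPM of at least 3, 2.52 ± 0.07 (5.73-fold; adjusted p = 1.1e-16), from 60.6 ± 2.51 to 347 ± 26.2 CPM. Insig1, a sterol sensor of the endoplasmic reticulum (2.16 ± 0.05), and Idi1, an isomerase of isoprenoid synthesis (2.10 ± 0.07), followed. Trib3, a pseudokinase induced by the integrated stress response, fell (−1.54 ± 0.09), as did Polr2a (−1.99 ± 0.28) and Hspg2 (−1.81 ± 0.22), both among the 84 transcripts above. Myog rose (0.90 ± 0.07) while Myod1 (−0.86 ± 0.07), Myf5 (−0.72 ± 0.06) and the Id genes Id1 (−1.27 ± 0.08) and Id3 (−1.22 ± 0.08) fell.

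All 20 cholesterol synthesis genes rose (median 1.39, adjusted p = 2.9e-128), with Msmo1 at 1.83 ± 0.07 and Hmgcs1 at 1.78 ± 0.06. All 25 mitosis genes rose (median 0.50, adjusted p = 4.0e-36), led by the spindle genes Nusap1 (0.96 ± 0.07), Bub1 (0.80 ± 0.06) and Ndc80 (0.70 ± 0.05), and all 8 condensin genes rose (median 0.44, adjusted p = 5.1e-09). 18 of 31 DNA replication genes rose and 3 fell (19 and 3 adjusted over the list alone, median 0.18, adjusted p = 0.0020, adjusted p = 0.19 with an estimated correlation), with Rrm1 at 0.47 ± 0.04 and, against the list, E2f1 at −0.38 ± 0.08. 11 of 15 cell cycle exit genes rose and 2 fell (median 0.42, adjusted p = 1.0e-08), with Ccng2 at 1.16 ± 0.05 and Gadd45b at 1.02 ± 0.11. 13 of 15 glycolysis genes rose and 1 fell (median 0.47, adjusted p = 3.7e-10), led by Pfkl (0.97 ± 0.06) and Aldoc (0.94 ± 0.23). 19 of 20 ribosome biogenesis genes fell and 0 rose (median −0.49, adjusted p = 9.8e-21), with Rrp12 at −0.91 ± 0.06 and Nop2 at −0.71 ± 0.05. 25 of 44 sarcomere genes rose and 1 fell (26 and 2 adjusted over the list alone, median 0.77, adjusted p = 8.0e-09, adjusted p = 0.052 with an estimated correlation), with Myh4 at 3.07 ± 0.58 and Lmod3 at 1.70 ± 0.16 against Des at −0.28 ± 0.05. 9 of 14 Id and Notch genes fell and 3 rose (median −0.49, adjusted p = 6.0e-06), although the Notch target Heyl (1.52 ± 0.17) and the ligand Dll1 (1.05 ± 0.14) rose. 3 of 7 smooth muscle markers rose and 0 fell (4 and 0 adjusted over the list alone, median 0.60, adjusted p = 5.3e-08), with the actin-binding Tagln at 1.67 ± 0.06.

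In all, 2719 genes were higher and 2634 lower at 12 h than in GM, and 432 changed at least 2-fold. The excess of higher genes was larger with RLE scaling (3010 higher, 2353 lower) and DESeq2 (2833, 2248). It was larger also without a count filter (3178, 2187) and with a CPM filter (3076, 2308). Counts stayed near even with upper-quartile scaling (2707, 2655), a replicate block (2646, 2574) and in the 6 libraries alone (2407, 2427). In the fits that left a library out 1848 to 2580 were lower, each below the main count. With the level of the 84 transcripts as a covariate, added after the data were seen, 1278 were higher and 1373 lower, and the calls of Des (−0.205), Aldoc (0.787), Cdkn1a (0.183), Myh8 (1.028) and the DNA replication, insulin-like growth factor and bone and cartilage lists were lost. The call of Ccnd1 (−0.17, adjusted p = 0.033) was also lost with RLE or total-count scaling, with either other filter and in 14 of the 18 fits that left a library out.

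After 24 h the replication and mitosis genes that had risen at 12 h lay below GM, and contractile genes had risen. Klhl40, which stabilises thin filament proteins, rose most (3.70 ± 0.15, 13-fold; adjusted p = 6.4e-15), with Insig1 (3.64 ± 0.05) and Idi1 (3.62 ± 0.07). The cystine transporter Slc7a11 (−3.85 ± 0.12), Trib3 (−3.65 ± 0.10) and the amino acid transporter Slc7a5 (−2.85 ± 0.07) had the largest falls. Myog had risen by 2.54 ± 0.07, the fusion genes Mymk and Mymx by 2.28 ± 0.11 and 3.40 ± 0.18, and the muscle creatine kinase Ckm by 3.58 ± 0.19.

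40 of 44 sarcomere genes rose and 0 fell (41 and 0 adjusted over the list alone, median 2.05, adjusted p = 2.1e-25), and 15 of 19 calcium handling genes rose and 0 fell (median 1.38, adjusted p = 4.0e-08). All 31 DNA replication genes fell (median −1.48, adjusted p = 1.3e-52), all 25 mitosis genes fell (median −0.93, adjusted p = 2.7e-23) and all 20 ribosome biogenesis genes fell (median −1.07, adjusted p = 7.3e-21). Cholesterol synthesis reached its highest median here, 2.61 (all 20 higher, adjusted p = 4.3e-104), with the decarboxylase Mvd at 3.49 ± 0.09 and the sterol dehydrogenase Nsdhl at 3.32 ± 0.07. 14 of 15 glycolysis genes rose and 1 fell (median 0.73, adjusted p = 2.7e-08, adjusted p = 0.076 with an estimated correlation), with Aldoc at 3.52 ± 0.19. In the stress response list Chac1 (−2.57 ± 0.12) and Asns (−2.32 ± 0.05), both targets of the transcription factor Atf4, fell (4 of 16 higher and 10 lower, median −0.29, adjusted p = 1.9e-05). 9 of 14 interferon response genes rose and 2 fell (median 0.72, adjusted p = 0.013, adjusted p = 0.095 with an estimated correlation), with Ifit3 at 2.15 ± 0.22 and Mx2 at 1.95 ± 0.61. In all, 4619 genes were higher and 4679 lower than in GM.

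At 48 h the lists of sarcomere, calcium handling and neuromuscular junction genes passed as higher. Casq2, calsequestrin of the sarcoplasmic reticulum, rose 5.52 ± 0.12 (45.9-fold; adjusted p = 2.1e-19) and Ckm 5.27 ± 0.17. Gm10800, a predicted gene of unknown function, also rose (5.40 ± 0.75), with a wide error. Slc7a11 (−3.61 ± 0.12), the monocarboxylate transporter family member Slc16a11 (−3.57 ± 0.10) and the proliferin gene Prl2c2 (−3.30 ± 0.08), which shares reads with near-identical copies, had the largest falls. Myod1 now lay above GM (0.62 ± 0.07), with Myog at 4.22 ± 0.07 and Mef2c, a partner of the MyoD family, at 1.65 ± 0.11.

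43 of 44 sarcomere genes rose and 0 fell (44 and 0 adjusted over the list alone, median 3.98, adjusted p = 2.0e-78), all 19 calcium handling genes rose (median 1.86, adjusted p = 2.9e-24) and all 9 neuromuscular junction genes rose (median 1.45, adjusted p = 8.7e-14). 9 of 13 genes of the insulin-like growth factor axis fell and 3 rose at 12 h (median −0.27, adjusted p = 0.017, adjusted p = 0.19 with an estimated correlation, call lost with the covariate for the 84 transcripts), while at 48 h 8 of 13 higher and 2 lower (median 0.35, adjusted p = 0.021, adjusted p = 0.21 with an estimated correlation), with Igf1 at 3.68 ± 0.14 and Igf2 at 2.10 ± 0.11. DNA replication (all 31 lower, median −1.58, adjusted p = 4.0e-41) and mitosis (all 25 lower, median −1.03, adjusted p = 4.4e-23) stayed below GM. In all, 4979 genes were higher and 5025 lower than in GM.

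At 60 h, the time also profiled by ATAC-seq and Hi-C, the largest rises against GM among genes with a mean log2 CPM of at least 3 were of contractile, calcium store and creatine kinase genes. Casq2 rose 6.74 ± 0.12 (107-fold; adjusted p = 6.6e-21), from 1.43 ± 0.139 to 153 ± 20.4 CPM, and Ckm 6.09 ± 0.16. The others of the 10 largest rises above that level were sarcomere genes: the myosin-binding protein Mybph (6.11 ± 0.10), the myosin light chains Mylpf (5.86 ± 0.08) and Myl4 (5.73 ± 0.12), the embryonic heavy chain Myh3 (5.66 ± 0.09), the troponins Tnnc1 (5.76 ± 0.09), Tnnt3 (5.63 ± 0.08) and Tnnc2 (5.61 ± 0.10), and the actin Actc1 (5.59 ± 0.12). The largest falls were of Prl2c2 (−4.30 ± 0.09), to 5.41 ± 0.686 CPM, and its relative Prl2c3 (−3.10 ± 0.09), the integrin chain Itgb7 (−4.14 ± 0.14), Slc7a11 (−3.42 ± 0.11), Trib3 (−3.16 ± 0.10) and the mitochondrial folate enzyme Aldh1l2 (−2.65 ± 0.05). The histone genes Hist1h2ae (−2.67 ± 0.10), Hist1h2bh (−2.63 ± 0.11) and Hist1h2ap (−2.63 ± 0.10) fell too; the reads of Prl2c and histone genes may be split between copies. Polr2a, of the 84 transcripts, lay at −2.61 ± 0.30 (adjusted p = 1.4e-07).

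Of the panel at 60 h, Myog had risen 29.1-fold (4.86 ± 0.07), Mef2c 2.24 ± 0.11, Myod1 0.69 ± 0.07, Mymk 4.91 ± 0.09, Mymx 6.32 ± 0.13, Myh8 5.69 ± 0.26, Myh7 4.20 ± 0.17, Acta1 5.38 ± 0.09, Ttn 3.46 ± 0.16, Des 1.08 ± 0.05 and the cell cycle inhibitor Cdkn1a 1.65 ± 0.05. Myf5 (−0.70 ± 0.06), Id1 (−1.93 ± 0.09), Id3 (−1.14 ± 0.08), Ccnd1 (−1.31 ± 0.06), Ccna2 (−1.48 ± 0.04) and the proliferation marker Mki67 (−2.21 ± 0.05) fell. Pax7, a satellite cell factor, was at 0.00 and did not pass.

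The lists of skeletal muscle genes passed as higher at 60 h. All 44 sarcomere genes rose (median 4.90, adjusted p = 7.5e-104). The adult and slow isoforms Myl2 (7.10 ± 0.91), Myh4 (6.50 ± 0.35) and Myh2 (6.06 ± 0.39) were among the largest rises, beside Mybph (6.11 ± 0.10). Developmental isoforms (all 6 higher, median 5.68, adjusted p = 2.7e-36), fast fibre isoforms (all 11 higher, median 5.48, adjusted p = 6.8e-39) and slow fibre isoforms (7 of 8 higher and 1 lower, median 4.51, adjusted p = 9.3e-15) passed, with the tropomyosin Tpm3 (−0.66 ± 0.04) against the slow list. All 19 calcium handling genes rose (median 2.41, adjusted p = 2.3e-31), with the calcium channel Cacna1s at 6.20 ± 0.16 and Hrc at 5.53 ± 0.12. All 9 neuromuscular junction genes rose (median 1.44, adjusted p = 3.3e-14), with the foetal acetylcholine receptor chain Chrng at 4.07 ± 0.09. 12 of 13 muscle energy isoforms rose and 0 fell (median 1.68, adjusted p = 5.5e-09), with Cox8b at 6.19 ± 0.36 and myoglobin Mb at 4.92 ± 0.15. 11 of 15 myoblast fusion genes rose and 3 fell (median 0.64, adjusted p = 9.7e-07), with Cav3 at 5.34 ± 0.29 and, against the list, Kirrel (−0.56 ± 0.07), Dock1 (−0.25 ± 0.07) and Rac1 (−0.20 ± 0.04). 7 of 11 myogenic factors rose and 1 fell (median 0.75, adjusted p = 8.7e-06), with Mef2a at 1.65 ± 0.06 and Tead4 at 0.98 ± 0.09.

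**Figure D4:**
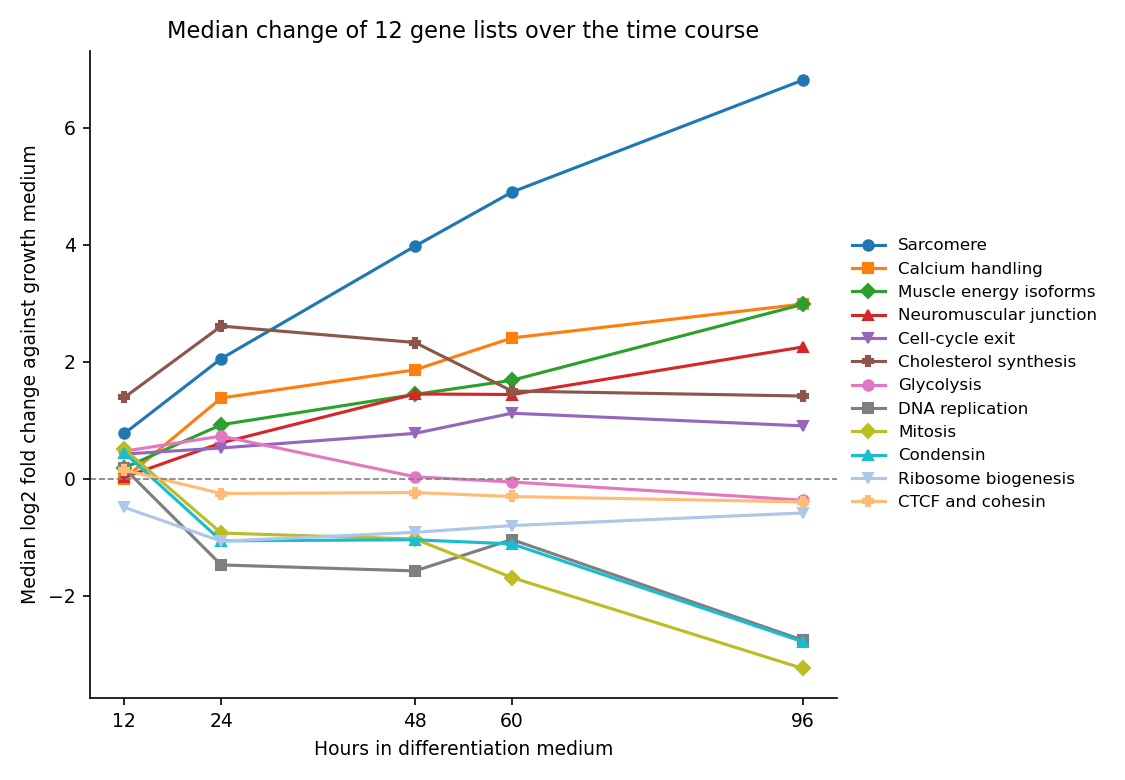
Lines give the median log2 fold change against GM (vertical axis) of the tested members of 12 lists at 12, 24, 48, 60 and 96 h in DM (horizontal axis). The sarcomere median climbed from 0.77 to 6.82, cholesterol synthesis peaked at 2.61 at 24 h, and mitosis passed from 0.50 at 12 h to −3.25 at 96 h.

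Proliferation lists fell at 60 h. 30 of 31 DNA replication genes fell and 0 rose (31 and 0 adjusted over the list alone, median −1.04, adjusted p = 2.6e-20), led by the licensing factor Cdt1 (−1.97 ± 0.10) and the polymerase Pole (−1.64 ± 0.07). All 25 mitosis genes fell (median −1.69, adjusted p = 3.6e-49), led by Cdc20 (−2.27 ± 0.06) and the kinase Plk1 (−2.23 ± 0.05), and all 8 condensin genes fell (median −1.12, adjusted p = 5.4e-10), led by Ncapd2 (−1.58 ± 0.04). All 20 ribosome biogenesis genes fell (median −0.80, adjusted p = 2.5e-10), with Nop56 at −1.44 ± 0.05 and nucleolin Ncl at −1.31 ± 0.08. 11 of 18 chromatin regulators fell and 4 rose (median −0.35, adjusted p = 0.0087): lamin Lmnb1 (−1.81 ± 0.07) and the maintenance methylation genes Uhrf1 (−1.49 ± 0.05) and Dnmt1 (−1.38 ± 0.05) fell, while the Polycomb methyltransferase Ezh1 rose (0.94 ± 0.04). CTCF and cohesin genes, 3 of 15 higher and 10 lower (median −0.31), did not pass (adjusted p = 0.098), although Rad21 (−0.90 ± 0.05) and Cdca5 (−1.18 ± 0.09) fell and Esco1 (0.55 ± 0.06) rose. 13 of 15 cell cycle exit genes rose and 2 fell (median 1.12, adjusted p = 9.7e-07), with Cdkn1c at 1.54 ± 0.28 and, against the list, the inhibitors Cdkn2d (−0.77 ± 0.08) and Cdkn2c (−0.40 ± 0.07).

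Cholesterol synthesis genes lay above GM at 60 h, all 20 higher (median 1.50, adjusted p = 5.5e-28). 10 of 12 imprinted genes rose and 1 fell (median 0.86, adjusted p = 2.9e-06), with Mest at 3.68 ± 0.09, the non-coding H19 at 3.14 ± 0.07 and, against the list, Peg10 at −1.14 ± 0.14. 9 of 12 satellite and reserve cell genes rose and 2 fell (median 1.23, adjusted p = 2.0e-05), with Heyl at 3.41 ± 0.15, Sox8 at 3.17 ± 0.15 and Spry1 at 2.59 ± 0.14. 10 of 14 autophagy and proteolysis genes rose and 2 fell (median 0.33, adjusted p = 0.0014), with the muscle ubiquitin ligase Trim63 at 4.17 ± 0.14 and, against it, Sqstm1 at −0.90 ± 0.05. 19 of 28 extracellular matrix genes rose and 6 fell (median 0.50, adjusted p = 2.0e-05, adjusted p = 0.20 with an estimated correlation), with periostin Postn at 3.41 ± 0.09 and decorin Dcn at 3.40 ± 0.07 against Nid1 at −1.44 ± 0.04. In the TGF-beta and BMP list (7 of 16 higher and 8 lower, adjusted p = 0.026, adjusted p = 0.15 with an estimated correlation) the median was −0.21 and the mean 0.41, so that median and test differed in sign; Fst, which binds activins and myostatin, rose (3.63 ± 0.11).

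These lists did not pass at 60 h: glycolysis (4 of 15 higher and 7 lower, median −0.06, mean 0.02, adjusted p = 0.61), nuclear-encoded respiratory chain (11 of 27 higher and 8 lower, median 0.05, adjusted p = 0.71), mitochondrial genome (2 of 13 higher and 3 lower, median −0.09, adjusted p = 0.87) and immediate early genes (5 of 20 higher and 11 lower, median −0.29, adjusted p = 0.32). Nor did the insulin-like growth factor axis (6 of 13 higher and 3 lower, 7 and 3 adjusted over the list alone, median 0.12, adjusted p = 0.12), interferon response (5 of 14 higher and 2 lower, adjusted p = 0.59, median −0.08, mean 0.16), the stress response (10 of 16 higher and 6 lower, adjusted p = 0.75, median 0.38, mean −0.24) or Id and Notch (5 of 14 higher and 6 lower, adjusted p = 0.88, median −0.20, mean 0.09). Single members did pass, such as Igf1 (3.86 ± 0.14), Igf2 (2.45 ± 0.11), Dll1 (4.24 ± 0.11), Fosl1 (−3.22 ± 0.16), Myc (−1.91 ± 0.13) and Asns (−1.78 ± 0.05). Among markers of other cell types, neuron genes passed (0 of 5 higher and 4 lower, median −0.77, adjusted p = 0.011, adjusted p = 0.068 with an estimated correlation), with the neurofilament Nefl at −1.52 ± 0.07. Smooth muscle (4 of 7 higher and 3 lower, adjusted p = 0.054), cardiac muscle (2 of 5 higher and 1 lower, adjusted p = 0.71), adipocyte (2 of 3 higher and 1 lower, adjusted p = 0.87) and bone and cartilage markers (0 of 4 higher and 3 lower, adjusted p = 0.054) did not. Too few members were tested for a list test in endothelium (all 2 higher), leukocytes (all 2 lower) and red cells (all 2 lower).

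In all, 5058 genes were higher and 4930 lower at 60 h than in GM, and 2545 changed at least 2-fold. With total-count scaling 4165 were higher and 5794 lower. More were lower than higher also with RLE (4925 higher, 5047 lower) and upper-quartile scaling (4974, 5011) and with DESeq2 (4727, 4860). The same held without a count filter (4834, 5211) and with a CPM filter (4598, 4858). With a replicate block (5021, 4890) or in the 6 libraries alone (4988, 4975) more were higher. In the fits that left a library out 4445 to 4921 were higher, each below the main count. With the level of the 84 transcripts as a covariate, 3449 were higher and 3490 lower, and the values moved to −0.74 for Polr2a and 4.47 for Ttn, while the sarcomere median was 4.99 and the calls of Dock1 (−0.027) and Peg10 (−0.415) were lost.

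By 96 h the median rises of the sarcomere and muscle energy lists had grown. Casq2 was 354-fold above GM (8.47 ± 0.12; adjusted p = 5.2e-23), with Myl4 at 8.35 ± 0.12 and Mybph at 8.16 ± 0.10, and Myog was 60.1-fold above it (5.91 ± 0.08). Prl2c2 (−6.71 ± 0.11), Itgb7 (−6.12 ± 0.17) and Prl2c3 (−5.70 ± 0.11) had the largest falls, and Ccna2 (−3.32 ± 0.05) and Mki67 (−3.42 ± 0.05) fell further below GM. All 44 sarcomere genes rose (median 6.82, adjusted p = 5.0e-117), with Myl2 at 12.04 ± 0.43. All 13 muscle energy isoforms rose (median 2.98, adjusted p = 2.2e-13). All 25 mitosis genes fell (median −3.25, adjusted p = 1.9e-81), all 31 DNA replication genes fell (median −2.76, adjusted p = 2.0e-53) and all 8 condensin genes fell (median −2.79, adjusted p = 1.4e-20). 10 of 15 CTCF and cohesin genes fell and 3 rose (10 and 4 adjusted over the list alone, median −0.40, adjusted p = 0.016, adjusted p = 0.31 with an estimated correlation), with the cohesin cofactors Cdca5 at −3.23 ± 0.10 and Esco2 at −3.09 ± 0.09. In all, 5319 genes were higher and 5216 lower than in GM, and 4628 and 5769 with total-count scaling.

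The steps between neighbouring times showed when each change was made. From 12 to 24 h Ckm (2.61 ± 0.16), Fndc1 (2.48 ± 0.14) and the imprinted Mest (2.47 ± 0.09) rose most, and the replication-dependent histone genes Hist1h2af (−2.66 ± 0.13), Hist1h3g (−2.58 ± 0.13) and Hist1h2an (−2.51 ± 0.14) fell most. All 31 DNA replication genes fell (median −1.59, adjusted p = 2.8e-79), led by Tk1 (−2.08 ± 0.06) and Mcm5 (−2.07 ± 0.07), and all 25 mitosis genes fell (median −1.47, adjusted p = 7.5e-71), led by Aurkb (−1.92 ± 0.05). 40 of 44 sarcomere genes rose and 0 fell (median 1.31, adjusted p = 2.4e-19). In this step 4258 genes rose and 4055 fell. With upper-quartile scaling 4953 rose and 3513 fell, and in the 6 libraries alone 3489 rose and 3889 fell. In the fits that left a library out 3728 to 4215 rose, each below the main count.

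From 24 to 48 h muscle genes rose further while glycolysis fell. Myl4 (2.42 ± 0.10), Casq2 (2.41 ± 0.09) and Tnnc1 (2.31 ± 0.07) rose most, and Prl2c2 (−2.27 ± 0.08), Prl2c3 (−1.86 ± 0.08) and Itgb7 (−1.78 ± 0.12) fell most. All 15 glycolysis genes fell (median −0.60, adjusted p = 6.4e-23), with the glucose transporter Slc2a1 at −1.15 ± 0.06 and Ldha at −0.84 ± 0.05. 19 of 20 cholesterol synthesis genes fell and 0 rose (median −0.37, adjusted p = 3.9e-14). 42 of 44 sarcomere genes rose and 0 fell (median 1.78, adjusted p = 3.0e-142). In this step 2683 genes rose and 2262 fell (54.3% higher), against 40.1% higher with total-count scaling. More fell than rose also with upper-quartile scaling (2366 rose, 2522 fell) and in the 6 libraries alone (2159, 2404). The same held without a count filter (2369, 2449) and with a CPM filter (2383, 2437). More rose with RLE scaling (2493, 2387), DESeq2 (2335, 2232) and a replicate block (2613, 2210). In the fits that left a library out 1910 to 2600 rose, each below the main count.

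From 48 to 60 h DNA replication genes rose while mitosis genes fell. 28 of 31 DNA replication genes rose and 0 fell (30 and 0 adjusted over the list alone, median 0.49, adjusted p = 1.5e-33), led by the cyclins Ccne2 (1.08 ± 0.10) and Ccne1 (0.86 ± 0.09) and the licensing factor Cdc6 (0.94 ± 0.08). 24 of 25 mitosis genes fell and 0 rose (median −0.52, adjusted p = 1.4e-61), led by the kinetochore genes Cenpf (−1.21 ± 0.06) and Cenpe (−0.98 ± 0.05) and by Cdc20 (−1.10 ± 0.06). Tagln (1.55 ± 0.06), the lipase inhibitor Angptl4 (1.40 ± 0.09) and Myl4 (1.34 ± 0.08) rose most, and Itgb7 (−1.41 ± 0.16), Mvd (−1.33 ± 0.08) and the small nuclear RNA Gm24497 (−1.59 ± 0.48) fell most. The call of Gm24497 was lost without the third 48 h library (−1.063), without the third 60 h library (−1.506) and with the covariate for the 84 transcripts (−1.686). Ttn was at −0.18 (adjusted p = 0.41), and at 0.383 with the covariate for the 84 transcripts, with which the call of Myh8 (0.725) was lost. All 20 cholesterol synthesis genes fell (median −0.58, adjusted p = 1.1e-54), and in the stress response list (9 of 16 higher and 1 lower, median 0.27, adjusted p = 1.7e-09) the endoplasmic reticulum chaperones Sdf2l1 (1.12 ± 0.09) and Calr (0.82 ± 0.04) rose. 24 of 27 tested nuclear-encoded respiratory chain genes rose and 0 fell (25 and 0 adjusted over the list alone, median 0.21, adjusted p = 1.9e-09, adjusted p = 0.11 with an estimated correlation) and 6 of 13 genes of the mitochondrial genome fell and 0 rose (7 and 0 adjusted over the list alone, median −0.30, adjusted p = 6.1e-04, adjusted p = 0.27 with an estimated correlation).

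In this step 2425 genes rose and 1732 fell, 58.3% higher, against 45.4% with upper-quartile scaling, 24.3% with total counts, 44.8% without a count filter and 47.1% with a CPM filter. With the covariate for the 84 transcripts 795 rose and 655 fell. Without the first 48 h library 2629 genes were called, 1192 of them higher, and without the second 1603 were higher. Over all fits that left a library out, 1192 to 2123 were higher, each below the main count of 2425.

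From 60 to 96 h replication genes fell again and sarcomere genes rose. Among genes with a mean log2 CPM of at least 3, the adult fast heavy chain Myh1 (2.68 ± 0.07), Myl4 (2.62 ± 0.08) and Polr2a (2.57 ± 0.30) rose most, and Nefl (−3.51 ± 0.11), Ccne2 (−2.99 ± 0.12) and the PCNA-binding 2810417H13Rik (−2.79 ± 0.10) fell most. The perinatal heavy chain Myh8, below that level, rose 2.92 ± 0.12. All 31 DNA replication genes fell (median −1.68, adjusted p = 6.3e-80), with Cdc6 at −2.70 ± 0.09, all 25 mitosis genes fell (median −1.56, adjusted p = 6.3e-80) and 43 of 44 sarcomere genes rose and 0 fell (44 and 0 adjusted over the list alone, median 1.63, adjusted p = 5.4e-92). 4 of 5 neuron markers fell and 0 rose (median −2.02, adjusted p = 2.3e-11), with Nefm at −2.37 ± 0.26. In this step 3455 genes rose and 3769 fell. With the covariate for the 84 transcripts 1192 rose and 1294 fell, and calls lost included those of Polr2a (0.263), Trib3 (0.717), Myod1 (0.276), Id1 (−0.541), Myf5 (−0.304), Pax7 (0.232) and the cholesterol synthesis list.

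The ATAC-seq lists compared accessible regions of proliferating cells and cells at 60 h. Near Myod1 (chromosome 7, 46376474 to 46379092) the 60 h list alone held a peak at 46370858 to 46371570, at a distance of under 10 kb from the gene, with an authors' fold of 4.70. Mef2c (chromosome 13, 83504017 to 83667079) had 6 peaks of the 60 h list alone, the strongest inside the gene at 83514980 to 83515683 (fold 6.22). Myh8, which encodes the perinatal myosin heavy chain, had 2 peaks, both of the 60 h list alone, 1 of them at 67313717 to 67314514 on chromosome 11 (fold 5.44). Ccna2 had 3 peaks of the GM list alone, the strongest at 36559686 to 36559959 on chromosome 3 (fold 2.93), and Myog had 1, at 134288297 to 134288805 on chromosome 1 (fold 3.99), close to the gene at 134290004 to 134292548. Along Ttn (chromosome 2, 76703980 to 76982557) the 60 h list alone had 104 peaks and the GM list alone 0, of which 4 had a −log10 q of at least 5 (median fold 1.44). The other panel genes had at most 4 peaks of either list alone, and Myf5, Mymk, Des and Ccnd1 had 0.

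**Figure D5:**
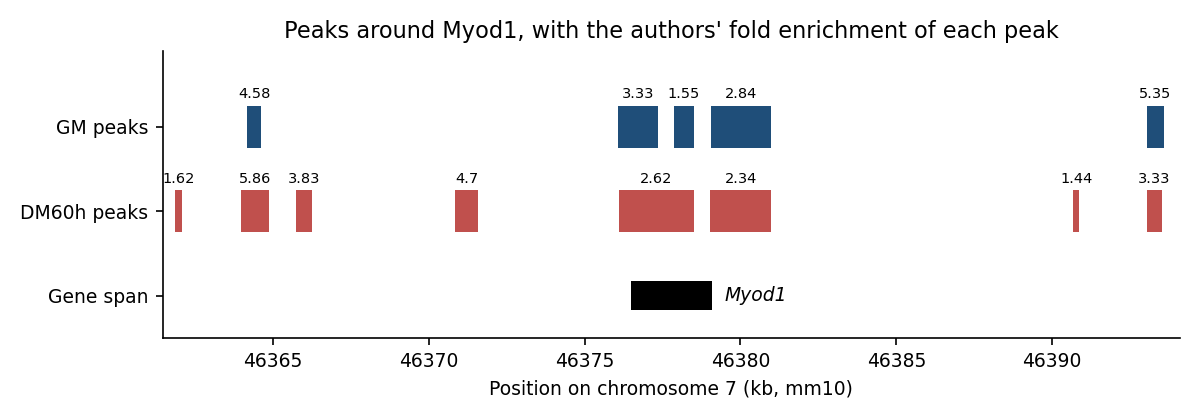
Peaks of the GM and 60 h lists around Myod1 on chromosome 7 (horizontal axis, position on mm10), drawn from start to end with the authors' fold enrichment above each peak and the gene (46376474 to 46379092) as a bar. The 60 h list alone holds the peak at 46370858 to 46371570 (fold 4.70), and folds are not comparable between the lists.

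The GM list held 181622 peaks over 113 Mb (median width 464 bp) and the 60 h list 189516 over 127 Mb (533 bp). Of the GM peaks 145968 (80.4%) overlapped a 60 h peak, and of the 60 h peaks 145440 (76.7%) overlapped a GM peak, which left 35654 peaks in the GM list alone and 44076 in the 60 h list alone. With an overlap of at least 50% of each peak these were 61875 and 69769. With a fold of at least 5 in both lists they were 15671 in GM against 7207 at 60 h. That cut kept 44556 GM and 36085 60 h peaks, and a peak under it in the other list counted as absent. Folds are not comparable between the lists, so the turned order of these counts is no comparison of the conditions. The peaks of 1 list alone at 1 bp of overlap were weaker than the shared peaks within their list, with a median fold of 1.82 against 3.48 in GM and 1.72 against 3.12 at 60 h. Of the peaks with a fold of at least 5, 266 in GM and 633 at 60 h had no peak in the whole other list, an alternative chosen after the data were seen.

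Peaks of 1 list alone were counted along 34 gene lists, each set against random lists matched on mean expression and not on gene length, without adjustment for the number of lists. Along sarcomere genes and 10 kb each side the 60 h list alone had 236 peaks and the GM list alone 49, a difference of 187 at percentile 100 of the random lists, and of 83 without Ttn. Calcium handling genes had 126 against 25 (percentile 99.8). Mitosis genes had 16 against 44 (percentile 0.005) and ribosome biogenesis genes 10 against 24 (percentile 1.0). The other 30 lists lay inside the central 95% of the random lists. They included myoblast fusion (63 against 33, percentile 93.1), muscle energy isoforms (8 against 15, percentile 7.3), DNA replication (22 against 29, percentile 4.6) and chromatin regulators (28 against 38, percentile 3.5). With random lists matched on gene span as well, an alternative chosen after seeing the data, sarcomere (percentile 100), calcium handling (99.6) and mitosis genes (0.105) stayed outside the central 95%, and ribosome biogenesis genes (4.49) moved inside. Of the other 30 lists, 7 then lay outside it, 6 of them above. Outside the rule, and chosen after their values were seen, the genes with the largest differences after Ttn were the cadherin gene Cdh13 (83 peaks of the 60 h list alone, 16 of the GM list alone), Celf2 (63, 8) and Dclk1 (39, 3), and in the other direction Ptprn2 (6, 27), Apba1 (0, 16), Col5a1 (6, 20) and Nid1 (1, 15).

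The relation of accessibility and expression at 60 h was asked over all placed genes. Genes with 60 h peaks alone within 2 kb of an end (141) had a median log2 fold change of 0.20, which was 0.197 above the 12807 genes with peaks of both lists (permutation p = 0.00106). Genes with GM peaks alone (129) had a median of −0.17, a difference of −0.174 (permutation p = 0.00475). The gene labels were also permuted only among genes of similar mean expression. Permutation p was then 0.0358 for genes with 60 h peaks alone and 0.0413 for genes with GM peaks alone. Both then lay only a little under 0.05. Within 500 bp the differences were 0.402 (permutation p = 1e-05, the smallest possible) and −0.219 (p = 4.0e-05 by permutation). With 10 kb the first difference turned to −0.184 (67 genes; permutation p = 0.0358), and among peaks with a −log10 q of at least 5 the second was −0.030 (permutation p = 0.581). Over the gene and 10 kb each side, 5070 genes with more 60 h-only peaks had a median of 0.11 and 4464 with more GM-only peaks one of −0.12 (difference 0.237; permutation p = 1e-05, the smallest possible).

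Domains were compared between proliferating cells and cells at 60 h. Myod1 lay in a TAD of chromosome 7 from 45960001 to 47120000 in GM and to 47080000 at 60 h. Myh3 and Myh8 shared 1 TAD, from 66960001 to 67800000 on chromosome 11 in both conditions. Mymx (45520001 to 46360000 on chromosome 17) and Id1 (152560001 to 153720000 on chromosome 2) also had the same TAD in both. Of the 16 panel genes that overlapped 1 TAD in each condition, 5 had the same TAD, Pax7 the other of them. The remaining 11 had a start or end that differed, 9 of them by 1 bin at 1 edge, within the tolerance used for boundaries. The other 2 were Cdkn1a (28640001 to 29600000 on chromosome 17 in GM, 28400001 to 29560000 at 60 h) and Ccna2 (35680001 on chromosome 3 to 36600000 in GM and to 36680000 at 60 h). Myog lay at a boundary in both, as did Pax7, which reached past the start of its TAD, and Ttn reached over 2 TADs in both. The lists held 2416 TADs in GM and 2368 at 60 h, with a median of 920 kb (quartiles 720 and 1200 kb) in each.

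Of 2467 GM boundaries 82.0% lay within 1 bin of a 60 h boundary, and of 2417 60 h boundaries 83.7% lay within 1 bin of a GM boundary. Random shifts gave 11.3% and 11.6% on average and at most 15.1% and 16.4% (permutation p = 0.001, the smallest possible). In the same bin alone the shares were 49.8% and 50.8%, against 3.81% and 3.89% on average for random shifts. Boundaries found in both conditions were stronger than the others of their list, with a median deposited score of 1.02 against 0.265 at 60 h and 0.923 against 0.255 in GM (permutation p = 1e-05, the smallest possible). TADs with the same start and end in both numbered 638. With 1 set per condition, no difference between conditions could be tested.

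Loops were called in GM alone or at 60 h alone for most entries, and muscle genes went both ways. Counted at any overlap of an anchor with the gene, Mef2c had 17 loops of GM alone, 10 of 60 h alone and 4 of both, and Ttn 5, 7 and 1. Both are long genes, and no anchor of the Ttn loops held an end of that gene. Acta1 had 2 loops of 60 h alone, and Ckm had 1, which joined 19400001 to 19425000 with 19575001 to 19600000 on chromosome 7. Id3 had 4 loops of GM alone, Mymx 3, Ccna2 and Mki67 2 each, and Myog and Id1 1 each. The loops of Mymk and Myh8, 1 each, were of both conditions, and Myod1 had 1 of GM alone and 2 of both. Of 63732 loops 32587 (51.1%) were of GM alone, 24031 (37.7%) of 60 h alone and 7114 (11.2%) of both, so that 60 h took 42.4% of the loops of 1 condition. Loops in both spanned a median of 325 kb, against 600 kb in GM alone and 550 kb at 60 h alone. A loop called in the other condition lay within 1 bin at both anchors for 27.5% of the loops of GM alone and 36.5% of the loops of 60 h alone. Loops of both conditions are not among the loops of these shares.

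Genes at loops of 60 h alone did not differ in expression change from genes at loops of GM alone by more than the spread. Their median log2 fold change at 60 h was −0.02 (1598 genes) against −0.01 (3185 genes), a difference of −0.014 (95% interval −0.055 to 0.023; permutation p = 0.425). Genes at loops of both kinds, 6868, were left out. With 10 kb around the anchors the difference was −0.039 (permutation p = 0.114).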

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

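Chosen only after their results were seen were the tests of other splits of the libraries and of library or RNA quality for the 84 transcripts. The 4 genes and 5 lists of this paragraph are given because their change against GM at 12 h and at a later time had opposite signs and the difference itself passed a test (n = 3 libraries per group), for lists with the preset correlation. The p-values are from edgeR's quasi-likelihood test for genes and from camera for lists, with the Benjamini-Hochberg adjustment. Myod1 was 1.86 higher at 96 h than at 12 h, with log2 fold changes against GM of −0.86 at 12 h and 1.00 at 96 h (adjusted p of the difference = 7.8e-16). Des was 1.83 higher at 96 h than at 12 h, from −0.28 to 1.55 (adjusted p = 1.3e-18). The difference for Ccna2 was −3.96, from 0.64 to −3.32 (adjusted p = 1.3e-23). For Mki67 it was −3.60, from 0.17 to −3.42 (adjusted p = 3.9e-23). The median of the mitosis list moved by −3.75, from 0.50 at 12 h to −3.25 at 96 h (adjusted p = 8.2e-107). That of the condensin list moved by −3.23, from 0.44 to −2.79 (adjusted p = 5.7e-27). The DNA replication list moved by −2.94, from 0.18 to −2.76 (adjusted p = 5.3e-59). The CTCF and cohesin list moved by −0.54, from 0.15 to −0.40 (adjusted p = 0.0029, adjusted p = 0.22 with an estimated correlation). The insulin-like growth factor axis moved by 0.63, from −0.27 at 12 h to 0.35 at 48 h (adjusted p = 2.7e-04, adjusted p = 0.061 with an estimated correlation). The 12 h calls of the DNA replication and insulin-like growth factor lists were lost with an estimated correlation and with the covariate for the 84 transcripts. The 12 h call of Des was lost with that covariate.

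The 84 transcripts that set the third 24 h library apart, Polr2a and Hspg2 among them, lay low at 12 and 60 h and high in GM and at 96 h. Cells of an earlier stage in that library are argued against, since its sarcomere genes differed from those of the other 24 h libraries by a median of −0.068, against 1.25 between 12 and 24 h. Library or RNA quality stays open: 100% of the 84 genes lay higher at 96 h than at 60 h, in libraries not used to choose them, against 46.9% of the other genes. Gene length stays open too, since the median genomic span of these genes was 89.0 kb, at percentile 100 of 10000 random lists matched on mean expression (random median 25.4 kb). A change with time in DM may add to the differences between groups, was not tested against these 2, and does not separate libraries within the 24 h group.

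DNA replication genes rose from 48 to 60 h while mitosis genes fell. The scaling of the libraries is argued against, since at least 25 of the 31 replication genes were called higher with TMM, RLE, upper-quartile, total-count and DESeq2 scaling. Library or RNA quality was checked through the level of the 84 transcripts alone. With it as a covariate the median of the replication list was 0.44, against 0.49 without it. Then 23 of 31 replication genes were called higher and 23 of 25 mitosis genes lower. The covariate's slope was estimated within groups, and in the third 24 h library replication genes differed by a median of −0.060 from the other 24 h libraries. An effect of the kind that set that library apart is thus argued against as the whole cause. Other differences in quality were not tested and stay open. A biological candidate explanation, a hypothesis found on these data and not itself tested, is that some cells may have entered S phase at 60 h without going on to mitosis. DNA content and cell division were not measured in these data.

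Along Ttn the 60 h list alone had 104 peaks and the GM list alone 0. The loose cutoff of the peak list stays open as untested: 2 tests of it along Ttn were tried after the values were seen and not kept, because Ttn was chosen for these peaks and they restated that. A general gain of such peaks along long genes that rise stays open too: genes of at least 50 kb that rose 2-fold at 60 h (388) had 1.47 more 60 h-only minus GM-only peaks per 100 kb than the other genes of that length (3141; permutation p = 1e-05, the smallest possible), and 1.38 more without Ttn. An opening of chromatin along Ttn with differentiation may also account for the peaks, and with 1 list per condition it was not tested.

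For the counts of genes called, the libraries were regrouped and fitted again. Over all 6 groups the true grouping gave 13161 genes and the highest of 99 random other groupings 2997. Thus 1 of 100 splits, the true one, gave as many genes, a share of 0.01, the smallest possible. A random labelling of these libraries is argued against. Regrouping cannot address differences between cultures, since the labels do not describe separate ones. In fits of the 6 libraries of each comparison with GM the real counts were 4834 at 12 h, 8813 at 24 h, 10022 at 48 h, 9963 at 60 h and 10259 at 96 h, and for the steps 7378, 4563, 4937 and 7075. The highest other split gave 0 in each, and 1 of 10 splits gave as many genes, the true one, but 10 splits are too few for a share under 0.05.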

How the results depend on the processing

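The alternatives chosen only after the data were seen were those with the covariate for the 84 transcripts, the fit of protein-coding genes alone, net peaks along genes, the peak filter on 1 list, and the random lists matched on gene span. The direction of values called in neither fit was not compared. Of the values for named genes under alternatives other than left-out libraries, 3579 kept their side of the threshold and, where called, their direction. Of the rest, 28 lost the call, 21 gained one and 1 was reversed. With a library left out, 6498 kept their side in that sense, 30 lost the call and 24 gained one. Of the list tests, 2119 did, 65 lost the call and 21 gained one, and with a library left out 5625, 9 and 36. Most lost list calls, 57, came with the estimated correlation. Of the counts of called genes, 292 lay within 1.5 times the main count and 43 did not, and with a library left out 501 did and 3 did not. The 6 alternatives for the TAD boundaries stayed above every random shift, with shares of 49.8% (GM) and 50.8% (60 h) in the same bin alone, 88.0% and 89.9% within 2 bins and 91.2% and 93.1% among the stronger boundaries. The 2 for loops and expression did not pass either.

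With a change of at least 2-fold added to the threshold, fewer genes pass by construction: 432 at 12 h (250 higher, 182 lower), 1991 at 24 h (1112, 879), 2602 at 48 h (1481, 1121), 2545 at 60 h (1369, 1176) and 3514 at 96 h (1739, 1775). For the steps to 24, 48, 60 and 96 h they were 1535 (733, 802), 573 (373, 200), 193 (82, 111) and 1181 (556, 625), and at any time 4983. At an adjusted p under 0.01, 1504 genes were lower at 48 h than at 24 h, and 2382 differed between 48 and 60 h (1406 higher, 976 lower). With total counts 998 were higher and 3101 lower in that step, where the median of all genes moved to −0.075. With the covariate, 2651 genes differed at 12 h (1278 higher, 1373 lower), 1450 from 48 to 60 h (795, 655) and 2486 from 60 to 96 h (1192, 1294). Ttn reversed from −0.18 to 0.383 between 48 and 60 h with it. The covariate's slope was estimated within groups, while its level also differed between them. Lost calls and lower counts may thus reflect a larger error as well as a smaller change, and these were not separated. Colq lost its call from 60 to 96 h although its value went from 2.107 to 2.277. Gm24497 lost it from 48 to 60 h although its value went from −1.588 to −1.686. The other lost calls of named genes, of 18 in all, came with a smaller value. With total counts the balance also turned at 24 h (5174 higher, 4078 lower), 60 h (4165, 5794) and 96 h (4628, 5769) against GM and from 60 to 96 h (3681, 3396), and 3215 were higher and 2124 lower at 12 h. Other settings turned it too. At 24 h more were higher with RLE (4825, 4493) and upper-quartile scaling (5159, 4190) and with DESeq2 (4591, 4328). At 48 h more were higher with upper-quartile scaling (5233, 4770). At 96 h more were lower with upper-quartile scaling (5020, 5493), without a count filter (5414, 5500) and with a CPM filter (4903, 4925). Total-count scaling differed from the main fit in leaving out the TMM factors, which had a mean of 1.009 in GM and 0.943 at 60 h. The median log2 fold change of all genes at 60 h against GM was then −0.0914, against 0.0067 in the main fit. What lies behind the TMM factors was not tested.

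With DESeq2 the counts were 5081, 8919, 9619, 9587 and 10254 against GM and 7913, 4567, 3833 and 6878 for the steps, and 12830 at any time. With 1 library left out they ranged from 4283 to 5616 at 12 h, 8546 to 9493 at 24 h, 9395 to 10189 at 48 h, 9339 to 10153 at 60 h and 10000 to 10736 at 96 h, and for the steps from 7510 to 8403, 4054 to 5100, 2629 to 4268 and 6466 to 7426. From 48 to 60 h, 1192 to 2123 genes were higher, the lowest without the first 48 h library (1603 without the second), and 1276 to 2233 lower. Left-out libraries ended single calls of Ccnd1 and Myh8 at 12 h, Pax7 at 24 h and in the step to 48 h, Cdkn1a and Myf5 in the step to 24 h, and Gm24497 in the step to 60 h. With the replicate number as a block, 5220 genes were called at 12 h, 9911 at 60 h and 13035 at any time, no call of a named gene or list was lost, and 2 named genes and 5 list tests gained one. The numbers gave no sign of a pairing: deviations correlated at a median of −0.011 over 45 pairs with the same number and 0.0042 over 90 other pairs, and 2 of 18 libraries correlated best with their own number.

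With an overlap of at least 50% of each peak, 61875 GM and 69769 60 h peaks were in 1 list alone. With a fold of at least 5 in both lists, which shortens both by construction, 44556 GM and 36085 60 h peaks were left, of which 28885 and 28878 overlapped and 15671 and 7207 did not. With the filter on 1 list against the whole other list, 12719 and 16794 were alone at a −log10 q of at least 5, and 266 and 633 at a fold of at least 5. Genes with 60 h peaks alone turned to −0.184 with 10 kb each side (permutation p = 0.0358), and genes with GM peaks alone lost the call at a −log10 q of at least 5 (−0.030, permutation p = 0.581). The cause was not tested in either case. With random lists matched on mean expression (5 classes) and gene span (10 classes), ribosome biogenesis genes moved to percentile 4.485, inside the central 95%, and 7 lists moved outside it: developmental sarcomere (99.9), fast (99.745) and slow fibre isoforms (98.795), neuromuscular junction (99.47), cholesterol synthesis (99.655), autophagy and proteolysis (99.975) and extracellular matrix (0.8). The cause was not tested. The stricter adjusted p, the unadjusted p and the 1.5-fold threshold planned for loops, and loops called at 0.01, were not run, because the loop table holds no p-value or fold. At this depth 1.5-fold changes were recovered in 85.1% of simulated cases, so that some changes of that size would be missed. The simulation changed far fewer genes than were called in the data and none with the lowest counts, so this share may not carry over.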

Other observations

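Of the tests in this part, that with the covariate for the 84 transcripts was chosen only after the result was seen, and Malat1 was named after its values were seen. Past 60 h smooth muscle markers went both ways, while calcium, junction and energy genes of skeletal muscle rose. From 60 to 96 h the smooth muscle markers calponin Cnn1 (−2.20 ± 0.41), Tagln (−1.82 ± 0.06) and the actin Actg2 (−1.63 ± 0.07) fell, while smoothelin Smtn (0.68 ± 0.09) rose (2 of 7 higher and 3 lower, median −0.22, adjusted p = 0.016, adjusted p = 0.17 with an estimated correlation). 18 of 19 calcium handling genes rose and 0 fell (median 1.16, adjusted p = 7.6e-28), with the calcium release channel Ryr1 at 1.95 ± 0.09 and the calcium pump Atp2a1 at 1.95 ± 0.08. 8 of 9 neuromuscular junction genes rose and 0 fell (median 0.75, adjusted p = 1.8e-09), with the synaptic collagen Colq at 2.11 ± 0.31. With the level of the 84 transcripts as a covariate, the calls of Cnn1 (−2.096), Smtn (0.337) and Colq (2.277) in this step were lost. 11 of 13 muscle energy isoforms rose and 0 fell (12 and 0 adjusted over the list alone, median 0.97, adjusted p = 5.0e-14), with Mb at 2.28 ± 0.09. 8 of 18 chromatin regulators fell and 5 rose (9 and 5 adjusted over the list alone, median −0.13, adjusted p = 0.0056), with Uhrf1 at −2.52 ± 0.05. Of the matrix genes 96 h after the switch, Postn (4.02 ± 0.09) and Dcn (3.94 ± 0.07) lay above GM and Nid1 (−1.88 ± 0.04) below it (20 of 28 higher and 6 lower, median 0.46, adjusted p = 0.0015, adjusted p = 0.35 with an estimated correlation). 8 of 12 satellite and reserve cell genes rose and 3 fell against GM (median 1.07, adjusted p = 0.0058, adjusted p = 0.057 with an estimated correlation), with the signalling inhibitor Spry1 at 3.22 ± 0.13 against Cd34 at −1.70 ± 0.05.

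Between 12 and 48 h the lists of growth factor signals and of imprinted genes passed in single steps. 9 of 13 genes of the insulin-like growth factor axis rose and 2 fell from 12 to 24 h (median 0.61, adjusted p = 0.0011, adjusted p = 0.090 with an estimated correlation), with Igf1 at 2.41 ± 0.18 and the binding proteins Igfbp3 at 1.28 ± 0.10 and Igfbp5 at 1.03 ± 0.05, against Igfbp2 at −0.48 ± 0.06. 8 of 12 imprinted genes rose and 0 fell from 24 to 48 h (median 0.44, adjusted p = 7.6e-08), with the adaptor Grb10 at 2.02 ± 0.53 and H19 at 1.80 ± 0.07. In the same step the TGF-beta and BMP list passed (7 of 16 higher and 1 lower, median 0.11, adjusted p = 3.0e-06), with Fst at 2.15 ± 0.11 and Ctgf, a matrix-bound growth factor, at 1.44 ± 0.07. Malat1, a nuclear long non-coding RNA, held 0.562 ± 0.0129% of the counts in GM, 1.22 ± 0.0378% at 24 h, 2.54 ± 0.136% at 48 h and 1.96 ± 0.221% at 96 h (SD, n = 3), and rose 2.17 ± 0.05 at 48 h against GM (adjusted p = 7.3e-19 in edgeR's quasi-likelihood test).

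The share of loops that crossed a TAD boundary was counted for each kind of loop. Of the loops of GM alone 42.3% spanned a GM boundary, of those of 60 h alone 35.4% and of those in both 17.6%. The differences were not tested, and the shares followed loop length, with medians of 600 kb in GM alone, 550 kb at 60 h alone and 325 kb in both.

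A first hypothesis was that anchors of loops called at 60 h alone hold more of the peaks found at 60 h alone. The 10856 anchors of 60 h loops had a mean of 0.149 more 60 h-only than GM-only peaks, against 0.103 at 19117 anchors of GM loops, a difference of 0.0457 (permutation p = 0.0005, 10000 permutations). The result was positive, and the difference was small beside its spread over anchors (SD 1.12 and 1.09). Anchors are not independent replicates, and loops and peaks come from 1 set per condition.

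A second hypothesis was that genes of 1 TAD change their expression together. Over gene pairs 50 to 500 kb apart, the mean absolute difference in log2 fold change at 60 h was 0.934 for 35159 pairs of 1 TAD and 0.949 for 10315 pairs across a boundary. Within classes of distance the difference was −0.00497 (permutation p = 0.7, 1000 permutations), and the result was negative: the test did not pass, which does not show that the pairs are alike.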
